A study of Sus scrofa with 6 samples.

How the data were processed

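RNA from the left atria of 6 male Lanyu miniature pigs, each 18 months old, was measured on a porcine Affymetrix expression array with 1 array per animal. The labels put the animals in 3 groups of 2. NC animals were normal controls, with no surgery recorded for them. Comparisons with NC therefore cannot separate regurgitation from the surgery that made it. MR animals had mitral regurgitation from a 2.8 mm hole in the posterior mitral leaflet and were killed 12 months after surgery. MRV animals had the same lesion and received valsartan, a blocker of the type I angiotensin II receptor, at 3.43 mg/kg/day from 1 week before surgery onward. Groups and replicate numbers were taken from the sample titles. The design text counts 6 separate pigs, so the spread between the 2 arrays of a group holds animal and technical variation together.

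The deposited values are 1 intensity per probe set and array on a linear scale, normalized between arrays by the authors before deposit. The submitters' processing notes name MAS5 and RMA without versions, and which of these gave the deposited intensity values is not given in the sources used here. The scale and the normalization were read from the values: they ran from 4.8 to 27167, and the array medians lay between 90.2 and 93.4. Raw scanner files were not used here. The number of arrays limits the precision of every value.

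The table held 24123 probe sets. The 124 control probe sets were left out of all tests, which left 23999. Gene symbols came from the platform annotation given with the series. It gave 1 symbol for 10069 probe sets, several for 198 and none for 13732, and no gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 9961 were found by Entrez gene ID in the RefSeq gene table of assembly Sscrofa11.1, and 0 symbols changed through that match. No genome coordinates are given, since the array annotation names no build.

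Intensities were tested as log2(intensity + 16), so all log2 differences are on that scale and understate changes of dim probe sets. Probe sets with a mean over the 6 arrays below the 40th percentile, an intensity of 60.8, were not tested. This left 14399 probe sets, of which 7139 had 1 symbol. For named genes and gene lists, each gene was represented by the probe set with the highest mean, which gave 5407 genes. Differences between groups were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 6 arrays together, with group means as the only terms. The fit had 3 residual degrees of freedom and 2.81 prior degrees of freedom. Standard errors (SE) are the moderated ones from this fit, and p-values were adjusted by Benjamini-Hochberg per comparison with a threshold of 0.05. The comparisons were MR minus NC, MRV minus MR and MRV minus NC. Probe sets at least 2-fold apart with no overlap between the arrays of the groups were counted as a description without a test, since 33.33% of unchanged probe sets show no overlap with 2 arrays against 2.

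Before the data were examined, 35 gene lists were fixed, 20 of pathways and 15 of cell types or regions that an atrial sample could hold. Of these, 33 had at least 3 measured members and were tested against the other genes with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. The neutrophil list had 0 tested members and the epicardium list 1, and neither was tested. A correlation estimated per list and the rotation test fry served as alternatives. fry asks whether the genes of a list move one way on balance and does not compare them with other genes, so it answers another question than camera. The rule for named genes was also fixed beforehand. It takes each gene past the threshold and fills up to 20 genes, or 10 for MRV minus NC, by smallest p among genes with a log2 difference of at least 0.5 and no overlap. It adds up to 4 members of each described list by moderated statistic, and 13 genes given wherever measured. COL3A1 lay below the filter, and ACTA1, COL1A1 and KCNA5 had no probe set with a single symbol. The lists that missed the threshold but are described were picked after the list results had been seen. The 8 genes in the plot of array intensities were picked, after their values had been seen, from the genes that the rule names.

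MR minus NC and MRV minus MR share the MR arrays, so their changes oppose each other by chance. The share of opposite signs over the 200 genes with the smallest p in MR minus NC, and the covariance over all 5407 genes, were set beside 100 simulations of unchanged groups. The same simulated values were used for the settings without an array or with different MR arrays, a step added after the data had been seen. The fit was tested on simulated data in which 200 of the 14399 probe sets were changed in MR. For MR minus NC it recovered 51.4% of changes of log2 1 and 91.6% of changes of log2 2, with 6.7 false calls among 149.9 calls per draw over 10 draws. These rates hold for that number and size of changes. Benjamini-Hochberg adjustment is stricter where fewer probe sets change, so they do not give the recovery in the real comparisons. A list of 16 genes shifted by 0.4 was called in 10 of 10 draws, in simulated genes that vary independently.

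Alternatives fixed beforehand were no filter and a filter at the 60th percentile, quantile normalization, median centring, pseudocounts of 1 and 64, an intensity trend with a robust prior, a fit on the 4 arrays of the groups compared, the replicate number as a block, leaving out probe sets that can hybridize with several transcripts, the mean or the other probe sets of a gene, and leaving out each array in turn. The signal of the 28S ribosomal RNA control probe set or the log2 ratio of 3' to 5' actin control signal as a covariate, the use of different MR arrays in the comparisons, and leaving out arrays or such probe sets for the 2-fold counts were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.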

Results

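Gene expression was measured in the left atria of 6 male pigs. The animals were normal controls (NC), animals with mitral regurgitation, a backflow of blood from ventricle to atrium (MR), and animals with mitral regurgitation treated with the angiotensin receptor blocker valsartan (MRV), with n = 2 per group. The array medians were alike, from 90.2 to 93.4 intensity units. The 2 NC arrays correlated less with each other (r = 0.959 across probe sets, which are not independent replicates) than the MR arrays did (r = 0.981) or the MRV arrays (r = 0.981), and NC2 correlated more closely with MRV2 (r = 0.984). The 28S ribosomal RNA control probe set read 117 and 468 in NC, 187 and 279.9 in MR, and 341 and 559 in MRV. The 3' actin control read 7859 and 10977 in MRV and from 13135 to 15543 on the other 4 arrays. The ratio of 3' to 5' actin signal, which rises as RNA degrades, was 1.61 and 1.91 in NC, 1.44 and 1.70 in MR, and 2.30 and 1.87 in MRV, and that of GAPDH lay between 1.17 and 1.34 on all 6 arrays.

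The comparison of MR with NC asked how mitral regurgitation, together with the surgery that made it, alters atrial RNA. Asparagine synthetase (ASNS), which makes asparagine from aspartate and glutamine, fell from 816 ± 52.0 in NC to 183 ± 14.3 in MR (SD, n = 2). Its log2 difference was -2.06 (SE 0.12, limma adjusted p = 0.0445), and it was the 1 probe set past the threshold among 14399. The hypertrophy and stretch list, genes induced in loaded heart muscle, shifted upward as a group, with 14 of 16 genes higher in MR and a median log2 difference of 0.26 (camera adjusted p = 6.77e-05; adjusted p = 0.546 with an estimated correlation). The adipocyte, immediate early, fatty acid and unfolded protein lists shifted downward. In all, 5 of the 33 lists passed the threshold with the preset correlation, and 0 passed with an estimated correlation. That loss does not rest on correlation between genes alone. With an estimated correlation, camera refers its statistic to the 3 residual degrees of freedom, which makes the threshold hard to reach for any list. With the preset it uses nearly as many degrees of freedom as there are genes, so genes rather than animals act as replicates. The unfolded protein list had an estimated correlation of -0.0052, below the preset 0.01, yet its unadjusted camera p rose from 0.00526 to 0.0496. With fry, which does not compare a list with other genes, 0 lists passed.

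The hypertrophy and stretch list was led by NPPB, the B-type natriuretic peptide that stretched heart muscle secretes, at 4302 ± 293 in NC and 8167 ± 122 in MR (log2 difference 0.92, SE 0.12, limma adjusted p = 0.694). The Z-disc protein gene NEBL read 246 ± 24.5 in NC and 465 ± 22.1 in MR. RCAN1, a regulator of calcineurin, read 672 ± 3.18 and 1138 ± 278, and the small heat shock protein gene HSPB7 read 2135 ± 77.9 and 3178 ± 502. Adjusted over the list alone, 4 of its 16 genes passed the threshold, against 0 adjusted over all probe sets. The 2 members with lower values, picked out after their values were seen, were XIRP1, at 1849 ± 94.3 in NC and 1493 ± 91.3 in MR, and FHL2, at 5007 ± 578 and 4358 ± 508. Without NC1 the list's median was 0.089 and its call ended (camera adjusted p = 0.0813), and without NC2 its median was 0.42. The number of lists called was 2 without NC1, 3 without MR1, 3 without MR2 and 3 with the actin ratio as a covariate, a choice made after the data had been seen.

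**Figure D1:**
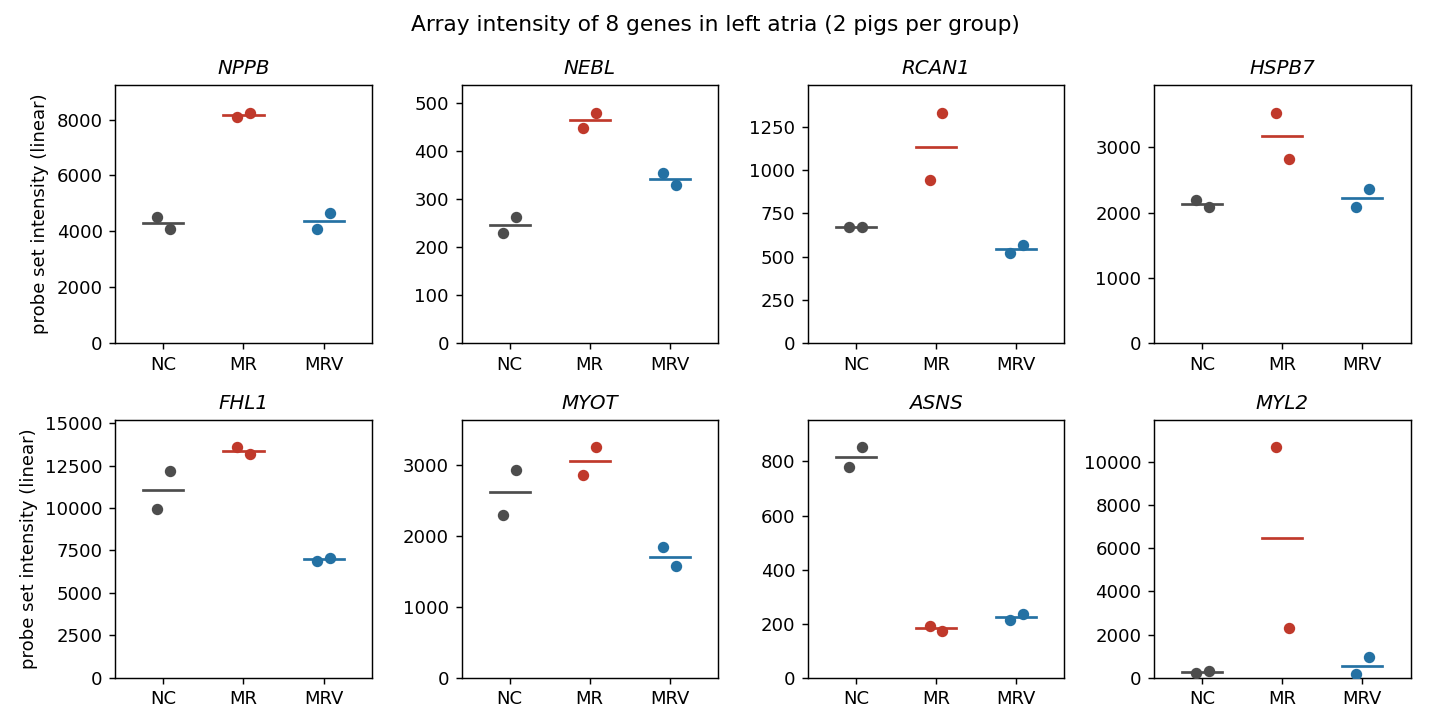
Array intensity (linear units) of 8 genes by group; each point is 1 animal and each bar the group mean of 2. NPPB read 8081 and 8253 in MR against 4076 to 4644 in the other groups, ASNS read 779 and 852 in NC against 173 to 237 elsewhere, and MYL2 differed widely between the MR animals.

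Of the adipocyte markers, 10 of 11 were lower in MR, with a median log2 difference of -0.42 (camera adjusted p = 0.00614; adjusted p = 0.546 with an estimated correlation). LIPE, hormone-sensitive lipase, read 182 ± 8.84 in NC and 105 ± 10.04 in MR. CIDEA, a lipid droplet protein gene, read 175 and 84.2 in NC and 62.0 and 65.2 in MR. The lipid synthesis gene DGAT2 read 324 in NC1 and from 90.7 to 112 on the other 5 arrays, and FASN read 472 in NC1 and from 219.5 to 292 elsewhere, while other FASN probe sets differed by 0.035 and -0.19 between MR and NC. Without NC1 the adipocyte median was -0.16 (camera adjusted p = 0.0590), and without MR2 it was -0.47 (camera adjusted p = 0.272). It was -0.67 without NC2 and -0.26 with no filter on dim probe sets, and the list kept its call in both cases. Adjusted over the list alone, 0 adipocyte markers passed.

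Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were lower in MR for 12 of 18 members, with a median of -0.28 (camera adjusted p = 0.0157; adjusted p = 0.941 with an estimated correlation). EGR1 read 795 ± 12.0 in NC and 506 ± 139.7 in MR, a log2 difference of -0.66 against -1.02 and -1.07 for its other probe sets, and FOSL2 read 149 ± 26.6 and 88.7 ± 8.13. The nuclear receptor gene NR4A3 read 950.45 ± 143 and 395 ± 289, and the RNA decay factor gene ZFP36 read 633 ± 99.0 and 440.0 ± 91.6. The call ended without NC1 (median -0.037, camera adjusted p = 0.151) and without MR1 (median -0.13, camera adjusted p = 0.404), and with the actin ratio as a covariate (median -0.22, camera adjusted p = 0.107). The median was -0.46 without NC2 and -0.14 with no filter. Adjusted over the list alone, 0 immediate early genes passed.

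Genes of fatty acid uptake and oxidation were lower in MR for 22 of 33 members, with a median of -0.097 (camera adjusted p = 0.0157; adjusted p = 0.647 with an estimated correlation). CPT1B, which carries fatty acids into mitochondria, read 1288 ± 94.0 in NC and 912 ± 37.6 in MR, and the retinoid receptor gene RXRG read 157 ± 9.62 and 106 ± 9.76. The subunits of the mitochondrial trifunctional protein, which oxidizes fatty acids, had opposite signs to the list: HADHB read 4872 ± 235 and 6503 ± 796, and HADHA read 1999 ± 149.8 and 2474 ± 115. The unfolded protein and heat shock list was lower for 22 of 32 members, with a median of -0.058 (camera adjusted p = 0.0347; adjusted p = 0.546 with an estimated correlation). It holds ASNS, whose log2 difference of -2.06 was far larger than the list's mean of -0.10, and the list was not tested without ASNS. The list's small heat shock genes HSPB8 and HSPB1 read 2789 ± 118 and 7052 ± 62.8 in NC against 2212 ± 39.2 and 5465 ± 37.5 in MR. DNAJB9, a chaperone of the endoplasmic reticulum, read 332 ± 34.2 and 409 ± 71.1, a log2 difference of 0.28, and other probe sets of the gene differed by 0.035 and 0.34. Adjusted over each list alone, 0 fatty acid genes and 1 unfolded protein gene, ASNS, passed. Without NC2 the fatty acid median was -0.056 and the unfolded protein median -0.052, both with a camera adjusted p = 0.617. Without MR2 these were -0.13 (camera adjusted p = 0.272) and -0.099 (camera adjusted p = 0.171), and without MR1 the unfolded protein median was -0.041 (camera adjusted p = 0.101). With the mean of all probe sets per gene the unfolded protein median was -0.034 (camera adjusted p = 0.198), and with the 28S covariate, added after the data had been seen, -0.056 (camera adjusted p = 0.0881). With the actin ratio as a covariate the calls of both lists ended, with a fatty acid median of -0.079 (camera adjusted p = 0.129) and an unfolded protein median of -0.046 (camera adjusted p = 0.254). With no filter the fatty acid median was -0.060.

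Other genes with the smallest p-values had limma adjusted p-values of 0.694 or more and are given as values. FABP7, a fatty acid binding protein gene, read 444 and 399 in NC and 43.3 and 105 in MR. The neurotrophin gene NTF3 read 173 ± 13.2 and 73.2 ± 10.6, the cell junction gene AMOTL1 read 981 ± 64.5 and 551 ± 15.4, and AKR1CL1 read 118 ± 23.1 and 44.9 ± 14.7. The log2 difference of AKR1CL1 was -1.15, and other probe sets of the gene differed by -0.24 and -1.25. MLF1, MSRB1 (a methionine sulfoxide reductase) and FKBP11 were lower in MR by log2 differences of -0.59, -0.55 and -0.80. Higher values in MR were those of CCNG2 (cyclin G2), C1H9orf16, INPP5F, PPIP5K2 and OCIAD2, with log2 differences of 0.72, 0.81, 0.66, 0.71 and 0.78. SLCO3A1, WIPI1, CD83, ZNF232 and SLC25A21 were higher by 0.63, 0.54, 0.53, 0.57 and 0.50, although another WIPI1 probe set differed by 0.029.

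Among lists that did not pass, collagens and fibrous matrix genes had a median of 0.013 (camera adjusted p = 0.911), with 13 of 25 higher, while the direction of the test was downward. In it THBS1 read 784 ± 54.6 in NC and 483 ± 124 in MR, and COL15A1 read 2544 ± 864 and 1563 ± 50.4. The list of TGF-beta and fibroblast activation had a median of 0.069 (camera adjusted p = 0.911). Its endothelin receptor gene EDNRA read 656 ± 22.9 and 422 ± 52.1, and the gene of its ligand, EDN1, read 85.1 ± 9.05 and 129 ± 12.0. In the renin-angiotensin list (median -0.030, camera adjusted p = 0.392), the angiotensin receptor gene AGTR1 read 594 ± 7.57 and 435 ± 117, and AGT, which encodes angiotensinogen, read 4209 and 1803 in NC and 1887 and 1097 in MR. Calcium handling genes (median -0.038, mean 0.0095, camera adjusted p = 0.911) held S100A1 at 1044 ± 329 and 2380 ± 612 and PPP1R1A at 310.1 ± 22.5 and 249 ± 17.3. Ion channel and gap junction genes (median 0.054, camera adjusted p = 0.472) held the potassium channel subunits KCNE1 at 291 ± 37.9 and 689.7 ± 51.9 and KCNE3 at 81.1 ± 14.5 and 126 ± 28.7.

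Genes of the sarcomere had a median of 0.046 (camera adjusted p = 0.392), with NEBL and MYL2 as the members that stood out. MYL2, the ventricular regulatory myosin light chain, read 203 and 325 in NC and 10693 and 2318 in MR, a log2 difference of 4.19 (SE 1.01, limma adjusted p = 0.999955). The ventricular list that also holds it had a median of 0.089 (camera adjusted p = 0.484), and its member MYL3 read 9323 ± 1045 in NC and 10456 ± 179 in MR. In the skeletal muscle list of 3 genes (median -0.064, mean 0.53, camera adjusted p = 0.986), TNNT1, slow skeletal troponin T, read 746 ± 353 and 2573 ± 214, and CKM read 12181 ± 37.8 and 10689 ± 639. The list of Schwann cells and neurons had a median of 0.17 (camera adjusted p = 0.463), with S100B at 509 ± 37.6 and 607 ± 8.41 and SOX10 at 61.1 ± 8.20 and 74.3 ± 0.424. The 28 lists that did not pass had adjusted p-values from 0.276 to 0.986.

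NPPB and AGTR1, described above, belong to the genes given in any case. Of the others, NPPA, the atrial natriuretic peptide, read 18639 ± 318 in NC and 19441 ± 554 in MR, and MYH7 read 21087 ± 690.1 and 21350.2 ± 427, near the highest value on any array, 27167. The calcium pump gene ATP2A2 read 15006 ± 5.80 and 14627 ± 922, ACE read 122 ± 13.8 and 120.3 ± 12.9, and the connexin genes GJA1 and GJA5 read 5733 ± 502 and 391.65 ± 65.5 in NC against 5130.05 ± 429 and 452 ± 186 in MR. SLN, sarcolipin, read 5369 and 9877 in MR against 8660 and 10033 in NC. NPPA, MYH7, ATP2A2, ACE, GJA1, GJA5 and SLN had limma adjusted p = 0.999955.

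Over all probe sets, 580 had an unadjusted limma p under 0.05 in MR minus NC, where 719.95 would by chance. At least 2-fold differences without overlap were seen for 55 probe sets, 21 higher and 34 lower in MR, and 26.8% of the tested probe sets showed no overlap, against 33.33% by chance. The call of ASNS ended without NC1, NC2, MR1 or MR2, with limma adjusted p-values of 0.251, 0.142, 0.876 and 0.466, with the actin ratio as a covariate (limma adjusted p = 0.445), and in 11 of 16 alternatives in all, over which its adjusted p ranged from 0.0342 to 0.876 and its log2 difference from -2.15 to -1.83. The 2-fold count was 131, 264, 97 and 99 without these arrays in the same order, where 1 array fewer makes overlap less frequent, and 28 with a pseudocount of 64.

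The comparison of MRV with MR asked what valsartan alters in the atria of animals with regurgitation. The hypertrophy and stretch list shifted downward, with 14 of 16 genes lower in MRV and a median log2 difference of -0.42 (camera adjusted p = 2.70e-06). The call was lost with an estimated correlation (camera unadjusted p = 0.0317, adjusted p = 0.995 with an estimated correlation). All lists of this comparison shared that adjusted value, so it does not rank this list among them. The separate question of whether the list's genes moved one way on balance, without a comparison with other genes, gave an adjusted p = 0.0963 with fry. NPPB read 8167 ± 122 in MR and 4360 ± 402 in MRV, a log2 difference of -0.91 (SE 0.12, limma adjusted p = 0.321). FHL1, a LIM protein gene of the sarcomere, read 13382 ± 281 and 6969 ± 147, RCAN1 read 1138 ± 278 and 543 ± 31.1, and the Z-disc gene MYOT read 3054 ± 279 and 1709.6 ± 195. Adjusted over the list alone, 8 of its 16 genes passed the threshold, against 0 adjusted over all probe sets. The list kept its call without each of the 4 arrays, with medians from -0.41 to -0.37 at the preset correlation. The MR arrays serve both this comparison and that with NC, so the opposite shifts of the list are not independent. The list of Schwann cells and neurons, which shares UCHL1 and CRYAB with it, was also lower in MRV for 7 of 8 genes, and the 3' actin control was lower in MRV. The actin ratio was higher in MRV (2.30 and 1.87) than in MR (1.44 and 1.70) without overlap. With the mean of all probe sets per gene the median of the hypertrophy list was -0.67. The number of lists called was 3 without MR1, 2 without MR2, 3 without MRV2, 3 with the 28S covariate and 4 with the actin ratio as a covariate.

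No probe set passed the threshold in MRV minus MR with limma (smallest adjusted p = 0.321), while 1047 had an unadjusted p under 0.05, 322 higher and 725 lower, where 719.95 would by chance. At least 2-fold differences without overlap were seen for 150 probe sets, 77 higher and 73 lower in MRV. The share without overlap was 42.4%, against 33.33% by chance. The 2-fold count was 280 without MR2 and 85 with a pseudocount of 64. With the 28S covariate, added after the data had been seen, 1 probe set was called.

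**Figure D2:**
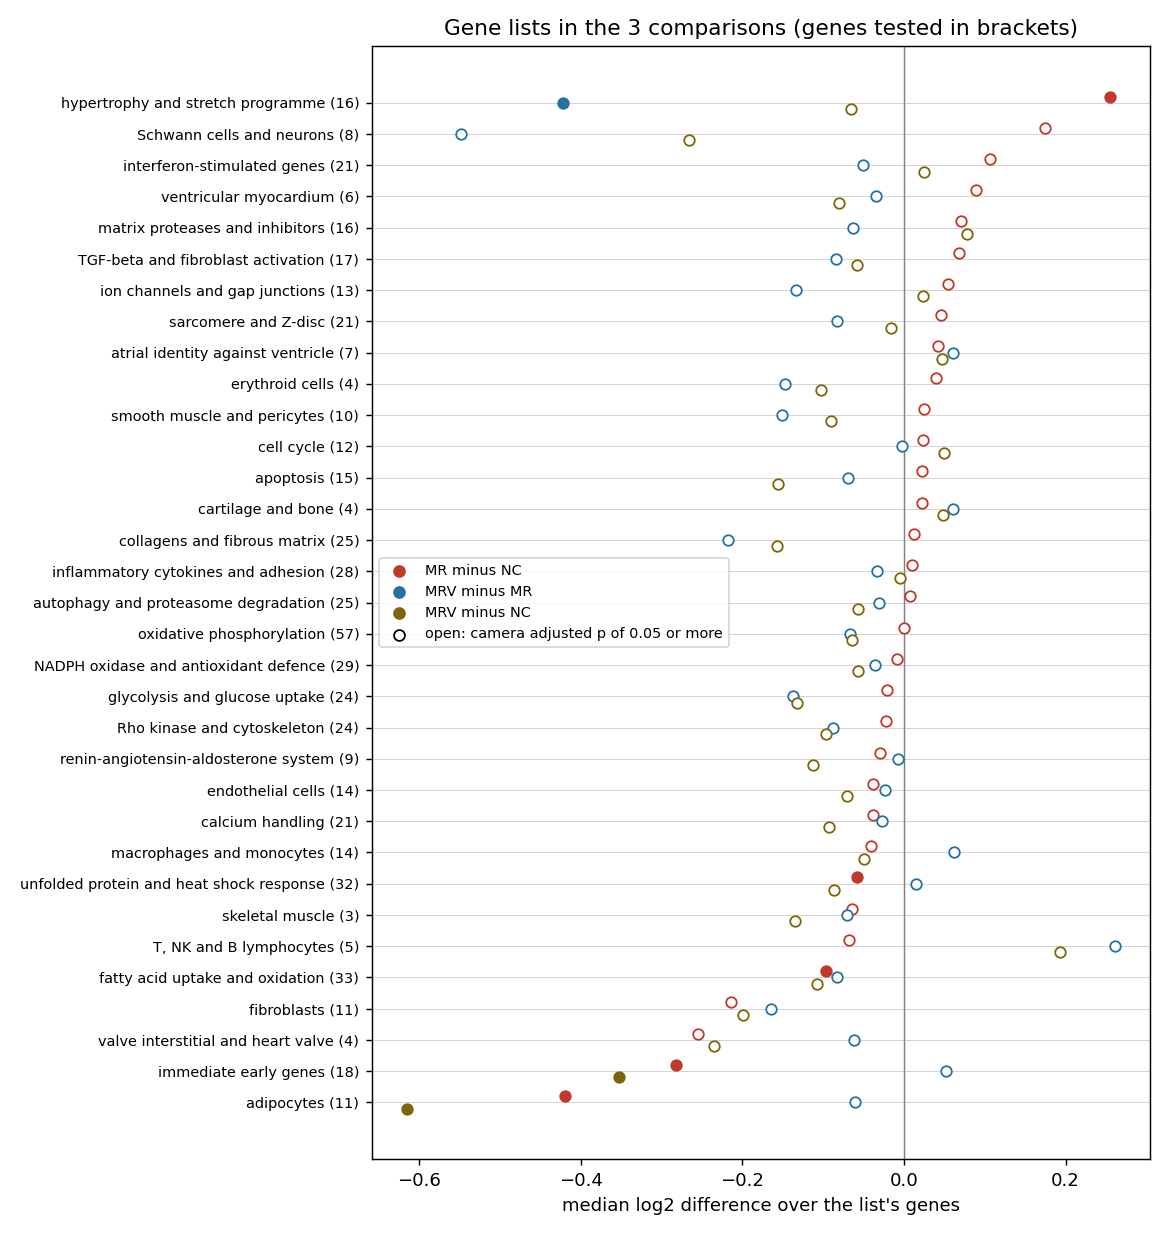
Median log2 difference of each of 33 gene lists (horizontal axis) in the 3 comparisons; filled points passed camera at a preset correlation of 0.01 and open points did not. The hypertrophy and stretch list lies at 0.26 in MR minus NC and at -0.42 in MRV minus MR, and the adipocyte list lies lowest in both comparisons with NC.

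The genes with the smallest p-values in MRV minus MR had limma adjusted p-values from 0.321 to 0.402 and are given as values. F3, the tissue factor that starts blood coagulation, read 991 ± 153 in MR and 236 ± 66.9 in MRV, a log2 difference of -2.01 (SE 0.23). SERPINB2, an inhibitor of plasminogen activators, read 1538 ± 103 and 761 ± 11.03, and DDAH1, which degrades an inhibitor of nitric oxide synthase, read 279 ± 28.4 and 96.9 ± 0.919. The smooth muscle gene CNN1 read 854 ± 68.0 and 508 ± 26.6, the secreted glycoprotein gene STC1 read 308 ± 91.6 and 121 ± 6.93, and the early response gene IER3 read 281 ± 2.83 and 121 ± 20.4. MAP1A read 778 ± 16.5 and 357 ± 46.9, although another of its probe sets differed by 0.011. The log2 differences of C1H9orf16, INPP5F, TTYH2, SELENOW, STBD1, WIPI1 and LOC100157017 were -0.98, -0.84, -0.85, -0.95, -0.88, -0.60 and -0.91, while other probe sets of STBD1 and WIPI1 differed by -0.51 and -0.036. Higher values in MRV were those of KIAA1671 (201 ± 42.9 in MR, 734 ± 65.1 in MRV), RUBCNL (100.2 ± 18.2 and 208 ± 4.31), the lysosomal membrane gene SCARB2 (325 ± 34.3 and 556 ± 24.5) and the transcription factor gene KLF11 (83.9 ± 16.5 and 183 ± 6.65). Another SCARB2 probe set differed by 0.27, against 0.75 for the one given.

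Of the other 32 lists none passed in MRV minus MR, with camera adjusted p-values from 0.107 to 0.995. Fatty acid genes had a median of -0.083 and a mean of 0.077 (camera adjusted p = 0.640), with 16 of 33 higher. Among them PDK4, which inhibits pyruvate dehydrogenase, read 1311 and 1501 in MR and 7036 and 4615 in MRV, and the lipase inhibitor gene ANGPTL4 read 109.8 and 106.7 in MR and 473 and 225 in MRV. PDK4 read 2003 and 5943 on the NC arrays. Sarcomere genes (median -0.083, camera adjusted p = 0.623) held TPM2 at 2557 ± 508 in MR and 1342 ± 99.4 in MRV, a log2 difference of -0.91 with other probe sets at -0.86, -0.91 and, for the dimmest, 0.011, and MYOM2 at 7776 ± 833 and 10557 ± 150. Collagens and fibrous matrix genes (median -0.22, camera adjusted p = 0.640) were lower for 18 of 25, with FBLN1 at 345 ± 40.3 and 250.1 ± 25.9 and CILP at 560 ± 37.8 and 242 ± 176, while another CILP probe set differed by 0.056.

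In the list of TGF-beta and fibroblast activation (median -0.084, camera adjusted p = 0.735), EDNRA read 422 ± 52.1 in MR and 645 ± 80.3 in MRV and EDN1 read 129 ± 12.0 and 85.5 ± 20.0. Renin-angiotensin genes (median -0.0071, mean 0.060, camera adjusted p = 0.985) held AGT at 1492 ± 559 and 2759 ± 461 and the protease gene CTSD at 718 ± 39.8 and 558 ± 95.6. AGTR1, the target of valsartan, read 435 ± 117 and 442 ± 38.5, and ACE read 120.3 ± 12.9 and 119 ± 3.32. Calcium handling genes (median -0.027, camera adjusted p = 0.948) held S100A1 at 2380 ± 612 and 1043 ± 450 and the calcium channel gene ORAI1 at 181 ± 18.0 and 141 ± 12.4. Ion channel genes (median -0.13, camera adjusted p = 0.995) held KCNE1 at 689.7 ± 51.9 and 391.7 ± 160.1 and GJA5 at 452 ± 186 and 279.65 ± 16.5.

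The ventricular list (median -0.034, camera adjusted p = 0.623) held MYL2 at 10693 and 2318 in MR and 152 and 954 in MRV, and MYL3 at 10456 ± 179 and 8396 ± 113. In the skeletal muscle list (median -0.071, camera adjusted p = 0.832), TNNT1 read 2573 ± 214 and 640 ± 448 and CKM read 10689 ± 639 and 11458 ± 241. The list of Schwann cells and neurons was lower for 7 of 8 genes (median -0.55, camera adjusted p = 0.107), with UCHL1, also in the hypertrophy list, at 2137 ± 197 and 909.9 ± 391 and GFAP at 120.2 ± 46.6 and 64.7 ± 5.09, where another GFAP probe set differed by 0.17. NPPA read 20104 ± 92.4 in MRV, MYH7 20859 ± 539.9, ATP2A2 15242 ± 49.6, SLN 8739 ± 296 and GJA1 6339 ± 849, with limma adjusted p-values against MR from 0.725 to 0.956. The ATP2A2 probe set given differed from MR by 0.06, and other probe sets of the gene by 0.22, 0.27 and -0.64.

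The comparison of MRV with NC asked what still differed from control atria under treatment. Immediate early genes shifted downward, with 13 of 18 lower in MRV and a median of -0.35 (camera adjusted p = 0.0305; adjusted p = 0.781 with an estimated correlation). Adipocyte markers shifted downward, with 10 of 11 lower and a median of -0.61 (camera adjusted p = 0.0204; adjusted p = 0.781 with an estimated correlation). Both lists also shifted downward in MR minus NC, which uses the same NC arrays. ATF3, a stress-induced transcription factor gene, read 1100 and 409 in NC and 89.1 and 49.0 in MRV. CYR61, a matrix-associated signalling protein gene, read 864 and 285 in NC and 154 and 116 in MRV, EGR1 read 795 ± 12.0 and 499.55 ± 25.2, and IER3 read 249 ± 62.2 and 121 ± 20.4. Of the adipocyte markers, FABP4 read 2911 and 1997 in NC and 1671 and 791 in MRV, GPD1 read 267 ± 80.2 and 156 ± 15.8, SCD read 488 ± 233 and 264 ± 43.3, and CIDEA read 129 ± 63.99 and 68.4 ± 21.8. Adjusted over the list alone, 2 immediate early genes and 0 adipocyte markers passed.

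The immediate early call ended without NC2 (median -0.45, camera adjusted p = 0.0827) and without MRV2 (median -0.35, camera adjusted p = 0.0574), and the adipocyte call ended without MRV2 (median -0.47, camera adjusted p = 0.0574). The adipocyte median was -0.27 without NC1 and -0.32 with the 28S covariate, and the list kept its call in both cases. Without NC1, 7 lists were called in place of 2, with median centring 4, with the 28S covariate 4, and with the actin ratio as a covariate 6, where the immediate early median was -0.55. ASNS read 816 ± 52.0 in NC and 225 ± 16.3 in MRV, a log2 difference of -1.79 (SE 0.12, limma adjusted p = 0.0622). XIRP1 read 1849 ± 94.3 and 1111 ± 29.6, CNN1 934 ± 59.3 and 508 ± 26.6, MSRB1 1278 ± 47.7 and 693 ± 59.6, and OXNAD1 466 ± 7.85 and 295 ± 12.1. F3 and MAP1A had log2 differences of -1.42 and -0.88, although another MAP1A probe set differed by 0.079. RUBCNL and KIAA1671 had log2 differences of 1.20 and 1.71. NPPB read 4302 ± 293 in NC and 4360 ± 402 in MRV (log2 difference 0.018, SE 0.12), and the hypertrophy and stretch list had a median of -0.066 (camera adjusted p = 0.380).

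No probe set passed in MRV minus NC with limma, while 761 had an unadjusted p under 0.05, where 719.95 would by chance. With the filter at the 60th percentile 2 were called, with a smallest adjusted p = 0.0496, that of ASNS, whose adjusted p ranged from 0.0496 to 0.944 over its alternatives. At least 2-fold differences without overlap were seen for 78 probe sets, 27 higher and 51 lower in MRV, and 33.1% of probe sets showed no overlap, against 33.33% by chance. The 2-fold count was 457 without NC2, 171 without MRV1 and 156 without MRV2, 51 with the stricter filter and 46 with a pseudocount of 64. The 31 lists that did not pass had camera adjusted p-values from 0.0568 to 0.964.

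Of the 200 genes with the smallest p in MR minus NC, 87% changed in the opposite direction in MRV minus MR. Unchanged groups that share the MR arrays gave 86.0% on average (SD 2.38, range 80.5 to 91 over 100 simulations). The covariance of the differences over 5407 genes was -0.0295 against a simulated -0.0259 (SD 0.0030), a difference of -0.0036, and the correlation was -0.499 against a simulated -0.501. With all 6 arrays both the share and the covariance lay within the simulated ranges. The simulated genes vary independently, so these ranges are narrower than for genes that vary together. With MR1 in the comparison with NC and MR2 in the other, a choice made after the data had been seen, the share was 58.5%, against a simulated 49.7% (range 40.5 to 57.5), and the covariance -0.0138 (simulated range -0.0123 to 0.0073). With MR2 first the share was 73%, against a simulated 49.5% (range 40.5 to 60), and the covariance -0.0063 (simulated range -0.0106 to 0.0113). The values also depended on the NC arrays. Without NC1 the share was 90% (simulated 79.3%, range 73.5 to 87.5) and the covariance -0.0427 (simulated -0.0258). Without NC2 these were 56.5% (simulated 79.4%, range 71 to 86) and -0.0162 (simulated -0.0260). Without MR2 the covariance was -0.0570 against a simulated -0.0515 (range -0.0634 to -0.0412). Without MR1 it was -0.0408 against a simulated -0.0526 (range -0.0657 to -0.0391), a difference in the other direction.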

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

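The 28S and actin ratio covariates, different MR arrays and arrays left out for 2-fold counts were chosen after the data had been seen; the cause of the changes below was not tested except where stated. Of 2179 alternative values of 135 gene differences, 2134 kept direction and side of the threshold, and 33 changed sign. The threshold was lost by 11, all of ASNS in MR minus NC, and gained by 1. Sign never changed for 114 differences. All differences but that of ASNS in MR minus NC missed the threshold in the main fit, so keeping their side means staying outside it. Many genes were picked for having no overlap between groups, so leaving out an array could not change their sign in that comparison. Of 104 alternative values of the 8 called list shifts none changed sign and 35 lost the threshold. Leaving out an array leaves 1 in its group, which is assumed to vary like the other arrays. Signals near the top of the range, as for NPPA and MYH7, and dim probe sets near the filter limit what differences can be seen.

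For MR minus NC the called probe sets went from 1 to 0 with no filter, quantile normalization, pseudocount 1, only the arrays of the 2 groups, the 28S covariate, the actin ratio covariate, and without NC1, NC2, MR1 or MR2 (0 to 0). Called probe sets went from 0 to 1 with the 28S covariate in MRV minus MR and from 0 to 2 with the stricter filter in MRV minus NC, where fewer probe sets were tested. The 2-fold counts of 55, 150 and 78 became 28, 85 and 46 with pseudocount 64, which shrinks folds by construction, and the last 51 with the stricter filter. Leaving out an array gave 97 to 264, 145 to 280 and 95 to 457.

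The lists called, 5, 1 and 2, were 0, 0 and 0 with an estimated correlation and with fry, and 2 to 6, 1 to 3 and 2 to 7 with an array left out. With the actin ratio covariate they were 3, 4 and 6. In MRV minus MR they were 3 with the 28S covariate and 2 with the mean of all probe sets of a gene, and in MRV minus NC 4 with median centring and 4 with the 28S covariate. The share of opposite signs, 87%, was 56.5% to 94.5% with an array left out and 58.5% and 73% with different MR arrays. The covariance, -0.0295, was -0.0570 to -0.0162 with an array left out, -0.0138 and -0.0063 with different MR arrays, where the shared term is removed, and -0.0262 with no filter.

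With the replicate number as a block, called probe sets were 0 in MR minus NC, 2 in MRV minus MR and 0 in MRV minus NC, lists called in MRV minus MR were 3, and the unfolded protein list in MR minus NC lost its call (adjusted p = 0.0805). Animals share only a number, so this is no established pairing: deviations of same-numbered arrays correlated at 0.34 for NC and MR, 0.21 for NC and MRV and 0.018 for MR and MRV.

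The actin ratio covariate gave -0.28 for SLN, -0.29 for AGTR1 and 0.015 for ACE in MRV minus MR. Quantile normalization gave -0.017 for NPPA in MRV minus MR and -0.025 for ATP2A2 in MRV minus NC. With an array left out, MR minus NC ranged from -0.015 to 0.051 for MYH7, -0.12 to 0.081 for ACE, -0.27 to 0.57 for GJA5, -0.79 to 0.083 for SLN and -0.10 to 0.026 for ATP2A2. MRV minus MR ranged from -0.18 to 0.70 for SLN, -0.23 to 0.31 for AGTR1, -0.10 to 0.089 for ACE and -0.0035 to 0.13 for ATP2A2. MRV minus NC ranged from -0.049 to 0.018 for MYH7, -0.20 to 0.013 for SLN, -0.13 to 0.074 for ACE and -0.076 to 0.11 for NPPB. Other probe sets with the opposite sign gave 0.035 for FASN in MR minus NC, and in MRV minus MR -0.64 for ATP2A2, 0.011 for MAP1A, 0.011 for TPM2, 0.056 for CILP and 0.17 for GFAP. In MRV minus NC they gave -0.83 for ATP2A2 and 0.079 for MAP1A.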

Other observations

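All tests of explanations in this part were chosen after the results they address had been seen. For the neuronal genes and the actin ratio covariate, the prediction was written before that test was run. None of the lists in this paragraph passed camera. Tested probe sets with an unadjusted limma p under 0.05 leaned lower in MRV: 725 lower and 322 higher against MR, and 528 lower and 233 higher against NC. The counts of lower genes below are not set against the share over all genes. Of the oxidative phosphorylation genes, 28 of 57 were higher in MR than in NC, while 47 of 57 were lower in MRV than in MR (median -0.067, adjusted p = 0.564) and 50 of 57 were lower in MRV than in NC (median -0.064, adjusted p = 0.0748). Of the glycolysis genes, 19 of 24 were lower in MRV than in MR (median -0.14, adjusted p = 0.623). The 5 measured lymphocyte genes were all higher in MRV than in NC (median 0.19, adjusted p = 0.0568) and in MRV than in MR (median 0.26, adjusted p = 0.128). Macrophage and interferon-stimulated genes had medians of 0.062 and -0.050 in MRV minus MR, with adjusted p = 0.759 and 0.976.

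The hypertrophy and stretch list was higher in MR and lower in MRV at the preset correlation. Its adjusted p was 0.546 and 0.995 with an estimated correlation (camera unadjusted p = 0.0432 and 0.0317) and 0.348 and 0.0963 with fry. The 28S probe set and the actin ratio, which may follow axes of RNA quality or labelling, were both without overlap between MR and MRV. With these as covariates the fall did not shrink: the median MRV minus MR was -0.47 and -0.45 in place of -0.42 (camera adjusted p = 5.80e-08 and 5.88e-07 at the preset correlation). Each slope rests on the differences within 3 groups of 2, so these fits cannot separate such axes from the treatment, and the axes stay open. Chance values of the shared MR arrays stay open: medians with a single MR array were at least 0.871 of those with both, which shows only that MR1 and MR2 lay close to each other. Another candidate is ventricular tissue in MR1, where MYL2 was highest. It predicts higher list genes in MR1 than in MR2 only if these genes are higher in ventricle than in atrium. The median difference MR1 minus MR2 was 0.0063 (upper quartile 0.109). No ventricular sample was measured, and the list holds NPPA, the atrial natriuretic peptide, so this difference cannot decide. An effect of the lesion and of valsartan, the difference the design names, stays open and untested, as do other differences in sampling. For the rise in MR, an effect of the surgery, recorded for MR and MRV only, stays open too. That rise may also rest on NC1, since without that array its median was 0.089.

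MYL2 was far higher in MR, and more so in MR1. Ventricular muscle in the MR samples may account for this, and the other 5 ventricular genes had a median difference of 0.018. None of these has both a low atrial level and a signal well above the dimmest probe sets, by bounds set after their values had been seen, so a small ventricular share cannot be told apart from a change within atrial muscle. Skeletal muscle stays open for the same reason. Of its 3 tested genes, TNNT1 was higher in MR (log2 difference 1.84) and was left out of the check after its value had been seen. The other 2 genes had a median of -0.13, and 0 were informative.

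The adipocyte list stood higher in NC1, with a median of 0.66 above the mean of the other 5 arrays, and both comparisons with NC draw on that array. FABP4, its most abundant member there, read 2911 in NC1 and from 791 to 2093 elsewhere, and PNPLA2 read 1454 and from 1421 to 1612. Of 16 adipocyte markers on the array, 11 passed the filter and were tested, and FABP4 and LPL are also in the fatty acid list. A candidate explanation is epicardial fat with a nerve ganglion in that sample. It was tested on neuronal genes that had not been looked at, after leaving out those in the list of Schwann cells and neurons. The 8 measured genes had a median of 0.23 in NC1 above the other arrays. This met the outcome written beforehand against the explanation, a median below 0.25. It lay below that bound by less than the spread of the genes, a margin that the written prediction did not name. Only 2 of the 8, SYT1 (1.78) and VSNL1 (1.46), exceeded 0.5, so the test does not decide; fat without nerve tissue and a biological explanation were not tested.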
